A study of Mus musculus with 6 samples.

How the data were processed

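Poly(A)-enriched RNA of the mouse lung epithelial line MLE-12 was sequenced, per the labels, in 6 libraries, 3 from cells under hypoxia and reoxygenation (I/R) and 3 from cells given dexmedetomidine before the same treatment (I/R + Dex). The labels call the 3 libraries of a group independent biological replicates and place all 6 in the same batch. Group and replicate number of each library came from its labels.

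The gene and transcript count tables were deposited by the authors as whole numbers, not normalised, per the file headers and the values. Per the submitters' processing notes, HISAT2 2.1.0, StringTie 2.2.4 and DESeq2 1.30 were used with the genome build GRCm39, and the notes used here give no role for any of them. The counting step, the annotation release and the treatment of reads with several matches are not given in the sources used here. Gene and transcript tables had equal totals in all 6 libraries. With transcripts assigned to genes by the authors' table or, where not listed there, by the reference annotation, the gene count equalled the sum of its transcripts in all libraries for 16389 of 16909 genes with a count, and 620 counted transcripts had no gene in either. The deposited FPKM tables were made by the authors, and the transcript FPKM followed the count divided by transcript length and a library-wide number, with a largest relative deviation of 3.93e-10. The authors' table of the comparison gives, per the file headers, a log2 fold change of I/R + Dex over I/R, a p-value and an adjusted p-value for each of 18021 transcripts, with mean FPKM per group. Lengths and coordinates of transcripts are those of the authors' table, per the file headers. The deposited enrichment tables for Gene Ontology (GO) and KEGG give, per the file headers, a ratio called the enrichment factor, p-values and the number of items per term. The tool behind the enrichment is not given in the sources used here.

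Gene symbols came from the authors' table for 11422 of the 16909 genes with a count and from a reference table of gene names for another 5189, while 298 had none. The reference annotation held here is GENCODE vM21 on another build, so it served for names, neighbouring genes, transcript sequences and the genes of unlisted transcripts, and no coordinate was taken from it.

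Total counts per library ranged from 2333546 to 2941989, so that a count of 0 allowed up to 1.02 to 1.29 CPM (counts scaled to library size), taking 3 counts as the floor. Molecules were not tagged, so floors cover counting error only, while the intervals also cover the spread between the libraries of a group. The median half-width of the 95% interval of a gene's log2 fold change was 1.37 for genes under 10 CPM on average, 0.76 from 10 to 30 CPM, 0.46 from 30 to 100 CPM and 0.26 above 100 CPM.

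The tests, the alternatives, 35 gene lists and the rule for naming genes were fixed before the data were examined. Gene counts were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood test after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Transcript counts were tested in the same way. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01. Of 901 list entries, 889 were matched by symbol and 5 by a synonym, and 7 had no match. Standard errors of log2 fold changes were derived from the F statistic, and CPM are given as mean ± SD over the 3 libraries of a group.

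Genes were named by a fixed rule. It took genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, up to 10 in each direction. In each list it took up to 4 members past the threshold, or up to 2 with the lowest p in a list that is discussed and has none. It took Ctnnb1, Tcf7l2, Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Ptgs2, Hmox1, Axin2, Lef1 and Adra2a in any case. It also took the 5 transcripts with the lowest p in each direction whose gene was not past the threshold. Genes outside the rule are said to have been chosen after their values were seen.

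Alternatives fixed in advance were DESeq2 size factors and upper-quartile factors in edgeR, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, and limma trend on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1 or without that filter. An absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn were fixed as well. For lists, camera with an estimated correlation and fry were fixed. Alternatives chosen after seeing the data added the counts of near-identical copies to each gene, or matched list genes by symbol alone. Copies were found with blastn 2.17.0 among the reference transcripts. The search used the coding transcripts of a gene, or all its transcripts where it had no coding one. A copy had 90% identity over at least 200 bases covering 50% of the gene's transcript. For a pseudogene, 20% of that transcript and 50% of the pseudogene were enough. A looser rule, 50% of either transcript, had been tried first and was replaced after its pairs were seen to join unrelated genes. The rule that was kept still joined some different genes, such as Fosl1 with Ccdc85b and Gins2 with Gse1. Matching by symbol alone had also been tried first, and synonyms were added once unmatched members were seen. Results under both earlier choices are given.

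The tests were tested on simulated data with the real means and library sizes and 200 changed features. Dispersions were taken from their trend with abundance, not from each feature. Among 7412 simulated genes, edgeR recovered 4.48% of 1.5-fold, 35.8% of 2-fold and 72.7% of 4-fold changes and called 8 unchanged genes, while DESeq2 recovered 5.97%, 38.8% and 72.7% and called 20. Among 9882 simulated transcripts, edgeR recovered 0% of the changes at each of these folds and called 0 unchanged transcripts, while DESeq2 recovered 0%, 0% and 1.52% and called 4. With camera, 4 of 4 simulated lists of 15 genes shifted 1.3-fold were called and 0 of 16 unshifted lists. For annotations of the authors' significant transcripts, genes were also counted once and drawn at random within 25 classes of the number of listed transcripts, with 5 or more pooled, and of the gene count. Figures were drawn with matplotlib 3.10.9.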

Results

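Transcripts were counted, per the labels, in MLE-12 cells, an immortalised mouse line derived from lung epithelium, after 12 h in 1% oxygen and 4 h of reoxygenation, a culture model of lung ischaemia and reperfusion. The identity of the cells rests on the labels, since epithelial genes such as Krt8, Krt18 and Sftpc had 0 counts in all 6 libraries, as described below. In the I/R + Dex group, 10 µM dexmedetomidine, an agonist of alpha-2 adrenergic receptors used as a sedative, was given for 12 h before hypoxia. Each group had 3 libraries, with total counts of 2607952, 2941989 and 2609058 in I/R and 2586743, 2333546 and 2420782 in I/R + Dex. Between 11473 and 12332 genes had a count in a library. Pseudogenes held 10.8% to 11.2% of the counts. Untreated cells were not analysed here, and the comparison was I/R + Dex against I/R. It addresses, per the title of the series, whether dexmedetomidine acts on ferroptosis, an iron-dependent form of cell death, through β-catenin and TCF4.

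Few genes passed the threshold between I/R + Dex and I/R, and the genes of ferroptosis and of Wnt signalling with enough counts to be tested were not among them. In simulated data edgeR recovered 4.48% of 1.5-fold and 35.8% of 2-fold changes over all genes, so small changes would mostly be missed. Among simulated genes with a mean count of 100 or more, edgeR recovered 65.6% of 2-fold changes. Ubald2, Rbm15b and Mrps2 rose in cells given dexmedetomidine, and Utp4 and Mboat7 fell. Ctnnb1, which encodes β-catenin, stood at 1413 ± 88.9 CPM in I/R and 1351 ± 127 CPM in I/R + Dex (SD, n = 3 each), a log2 fold change of -0.06. Gpx4, whose product reduces lipid hydroperoxides and limits ferroptosis, stood at 183 ± 33.4 and 154 ± 6.93 CPM (SD, n = 3 each).

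In edgeR, 5 of 7412 tested genes passed an adjusted p of 0.05, 3 higher and 2 lower in I/R + Dex, and 251 genes, 3.39%, had an unadjusted p under 0.05. DESeq2 called 17 genes and limma voom called 1. Other splits of the 6 libraries into 3 and 3 gave 0 to 5 genes in edgeR and 12 to 34 in DESeq2. Without I/R replicate 2, edgeR called 0 genes, and without any other single library it called 3 or 4, of which at most 1 was among these 5.

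Rbm15b, which encodes an RNA-binding protein of the m6A methylation machinery, rose from 33.3 ± 4.78 to 108 ± 4.6 CPM, a log2 fold change of 1.70 with a standard error of 0.15 (edgeR adjusted p = 0.0299). It lies on chromosome 9 at 106758117 to 106764627 in GRCm39. Ubald2 (chromosome 11, 116324920 to 116329903) rose from 3.82 ± 1.63 to 91.3 ± 25.9 CPM, a log2 fold change of 4.57 ± 0.37 (SE, edgeR adjusted p = 0.0299). Its near-identical copy Gm7367, chosen after its values were seen, held 328 to 449 counts in I/R and 237 to 338 in I/R + Dex, and 74.4% of the counts of both genes. The sum of both genes had a log2 fold change of 0.49 ± 0.14 (SE, edgeR adjusted p = 0.999). Mrps2, a protein of the mitochondrial ribosome encoded on chromosome 2 at 28358102 to 28361177, rose from 0.98 ± 0.2 to 16.4 ± 2.98 CPM, a log2 fold change of 4.00 ± 0.41 (SE, edgeR adjusted p = 0.0411). These counts lay on a transcript without a defined coding sequence.

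Utp4, a factor of ribosome assembly encoded on chromosome 8 at 107620283 to 107649720, fell from 31.5 ± 4.63 to 0.55 ± 0.48 CPM, a log2 fold change of -5.73 with a 95% interval from -7.08 to -4.38 (edgeR adjusted p = 0.0411). Its counts in I/R were 87, 77 and 92, of which 73, 65 and 92 lay on a transcript with a retained intron, against 2, 2 and 0 in I/R + Dex. Mboat7, a lysophospholipid acyltransferase gene on chromosome 7 at 3680788 to 3696522, fell from 46.3 ± 7.27 to 8.27 ± 2.09 CPM, a log2 fold change of -2.48 ± 0.27 (SE, edgeR adjusted p = 0.0421).

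**Figure D1:**
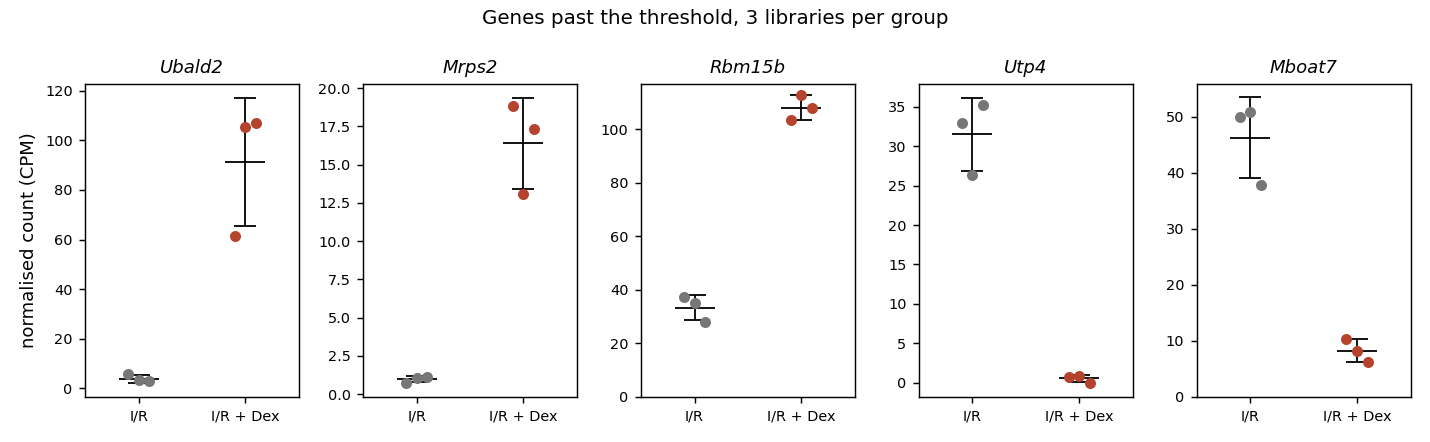
Normalised counts (CPM, vertical axes, different scales) of the 5 genes past the threshold in the 3 I/R libraries (grey) and the 3 I/R + Dex libraries (red), with mean and SD as bars. Ubald2, Mrps2 and Rbm15b were higher in all I/R + Dex libraries, Utp4 and Mboat7 lower in all of them.

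Among the ferroptosis genes fixed in advance, Slc7a11, the cystine transporter subunit, had a log2 fold change of 0.04 (95% interval -0.28 to 0.36). For Acsl4, whose product activates polyunsaturated fatty acids for insertion into lipids, it was 0.07 (-0.22 to 0.36). Gpx4 had -0.25 (-0.58 to 0.08) and Fth1, the ferritin heavy chain, 0.16 (-0.11 to 0.43). The transferrin receptor gene Tfrc was near the lower limit of the filter at 5.71 ± 2.11 and 4.53 ± 3.23 CPM, with a log2 fold change of -0.33 and a wide interval from -1.84 to 1.18. These 5 had an edgeR adjusted p above 0.99 and groups that overlapped. Ptgs2 had 0 counts in all 6 libraries. Hmox1, the haem oxygenase gene, was below the filter with 16, 24 and 10 counts in I/R and 6, 6 and 6 in I/R + Dex, so the groups did not overlap, and edgeR without a filter gave a log2 fold change of -1.27 (edgeR adjusted p = 0.858, unadjusted 0.0902). Of the counts of Gpx4 and its 2 counted copies, 72% lay on the copies. With these added, the log2 fold change was -0.40 ± 0.45 (SE, edgeR adjusted p = 0.999), so the interval of Gpx4 alone does not hold for the family. The copy Gpx4-ps2, chosen after its values were seen, held 1182 to 1342 counts in 5 libraries and 15 in I/R + Dex replicate 3.

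Of 28 genes on the ferroptosis defence list, 16 had enough counts to be tested, and of these 0 passed the threshold over all genes and 0 when adjusted over the list alone, with a median log2 fold change of 0.03 (camera adjusted p = 0.941). Its lowest p values belonged to Vkorc1l1, with 24.8 ± 9.79 and 46.3 ± 11.9 CPM, and Acsl3, with 112 ± 9.86 and 90.03 ± 18.1 CPM. Of the counts of Vkorc1l1 and its 2 counted copies, 70.4% lay on the copies, and with these added its log2 fold change went from 0.90 ± 0.33 to -0.08 ± 0.14 (SE, edgeR adjusted p = 1 and 0.999). Of 32 genes that promote or mark ferroptosis, 17 were tested and gave 0 calls on both scales and a median of 0.02 (camera adjusted p = 0.941). Sat1, a polyamine acetyltransferase gene of that list, stood at 450 ± 54.2 and 311 ± 55.2 CPM (log2 fold change -0.53, edgeR adjusted p = 1 and 0.13 when adjusted over the list alone). The 14 tested of 24 genes of iron handling had 0 calls and a median of 0.14, and the 16 tested of 33 targets of NRF2, the antioxidant regulator, 0 calls and a median of -0.03 (camera adjusted p = 0.941 for both).

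In the Wnt pathway, Tcf7l2, which encodes TCF4, had 53.3 ± 7.5 CPM in I/R and 49.5 ± 10.8 in I/R + Dex, a log2 fold change of -0.11 (95% interval -0.59 to 0.38). The 95% interval for Ctnnb1 ran from -0.26 to 0.13. The 28 tested of 40 pathway components had 0 calls and a median of -0.02, and the 10 tested of 28 targets of β-catenin and TCF had 0 calls and a median of -0.06 (camera adjusted p = 0.941 for both). Among the targets, the lowest p values were those of Jun, at 247 ± 5.95 and 276 ± 5.71 CPM, and Sox4, at 491 ± 24.2 and 446 ± 16.7 CPM. The direct target Axin2 had 3, 4 and 3 counts in I/R and 0 in each I/R + Dex library, so the groups did not overlap, and Lef1 had 0 counts in I/R and 2, 3 and 0 in I/R + Dex. Both were below the filter, and at 0 counts in a whole group no fold can be given. Without a filter neither passed the threshold (edgeR adjusted p = 0.858 for both, unadjusted 0.0604 for Axin2 and 0.109 for Lef1). The receptor gene Adra2a had 2, 0 and 0 counts in I/R and 2, 0 and 6 in I/R + Dex.

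**Figure D2:**
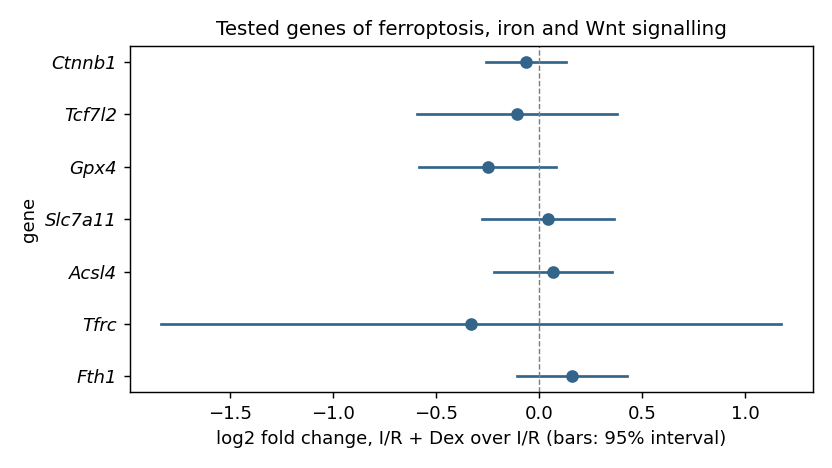
Log2 fold changes of I/R + Dex over I/R (horizontal axis, points) with 95% intervals (bars) of the 7 tested genes fixed in advance, from 3 libraries per group. All 7 intervals include 0, that of Tfrc from -1.84 to 1.18.

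Of 35 gene lists, 30 had at least 5 tested members. With camera, 0 passed an adjusted p of 0.05 and 2 had an unadjusted p under 0.05, with an estimated correlation 0 passed, with a smallest adjusted p = 0.944, and with fry 0 passed. Of 454 tested members, 0 passed over all genes. Adjusted over the list alone, 2 lists had 1 member past the threshold each. These were Shmt2, the mitochondrial serine hydroxymethyltransferase of the integrated stress response list, at 30.3 ± 3.84 and 10.3 ± 1.98 CPM (log2 fold change -1.56, edgeR adjusted p = 0.00584 adjusted over the list alone and adjusted p = 0.301 over all genes), and Klf6, an immediate early gene, at 250 ± 12.9 and 326 ± 12.1 CPM (log2 fold change 0.38, edgeR adjusted p = 0.0271 and 0.746).

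Targets of hypoxia-inducible factors had a median of -0.16, with 16 of 20 members below 0 (camera adjusted p = 0.372, unadjusted 0.0248). Pdk1 stood at 47.9 ± 1.63 and 37.0 ± 4.91 CPM and Loxl2 at 201 ± 9.77 and 172 ± 16.2 CPM. Replication-dependent histone genes, whose mRNAs mostly lack poly(A), had the smallest camera p, 0.00855, with a median of 0.21 (adjusted p = 0.256). Immediate early genes had a median of 0.10 and cholesterol synthesis genes -0.19 (camera adjusted p = 0.636 for both). Glycolysis, nuclear respiratory chain and mitochondrially encoded genes had medians of 0.02, 0.07 and -0.02, and ribosomal proteins 0.00 over 59 genes (camera adjusted p = 0.941 for each). The stress lists gave medians of -0.08 for the integrated stress response, -0.09 for ER chaperones and -0.07 for heat shock proteins. For genes of inflammation under NF-κB the median was 0.06, for apoptosis 0.08 and for p53 targets -0.13. It was -0.01 for both replication and mitosis genes, -0.12 for fatty acid synthesis, -0.03 for adrenergic signalling, 0.03 for mesenchymal and matrix genes, -0.01 for autophagy and lysosome genes and 0.01 for clock genes. All of these had a camera adjusted p = 0.941. Median, mean and camera direction differed in sign for 10 lists, those of ferroptosis promotion, Wnt components, NF-κB inflammation, p53 targets, replication, mitosis, alveolar type II, autophagy and lysosome, ribosomal proteins and the clock.

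Among markers of cell types, alveolar type II genes had a median of -0.16 over 5 tested members, fibroblast genes -0.06 and leukocyte genes 0.25 (camera adjusted p = 0.941 for each). Interferon response, alveolar type I, endothelial, epithelial junction and xenobiotic lists had 2, 2, 0, 4 and 3 tested members and were too small to test. Of 22 epithelial adhesion and junction genes, 12 had 0 counts in all libraries, and 10 of the 20 alveolar type II genes did. Among these, chosen after their values were seen, were the keratin genes Krt8 and Krt18 and the surfactant genes Sftpa1, Sftpb and Sftpc.

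**Figure D3:**
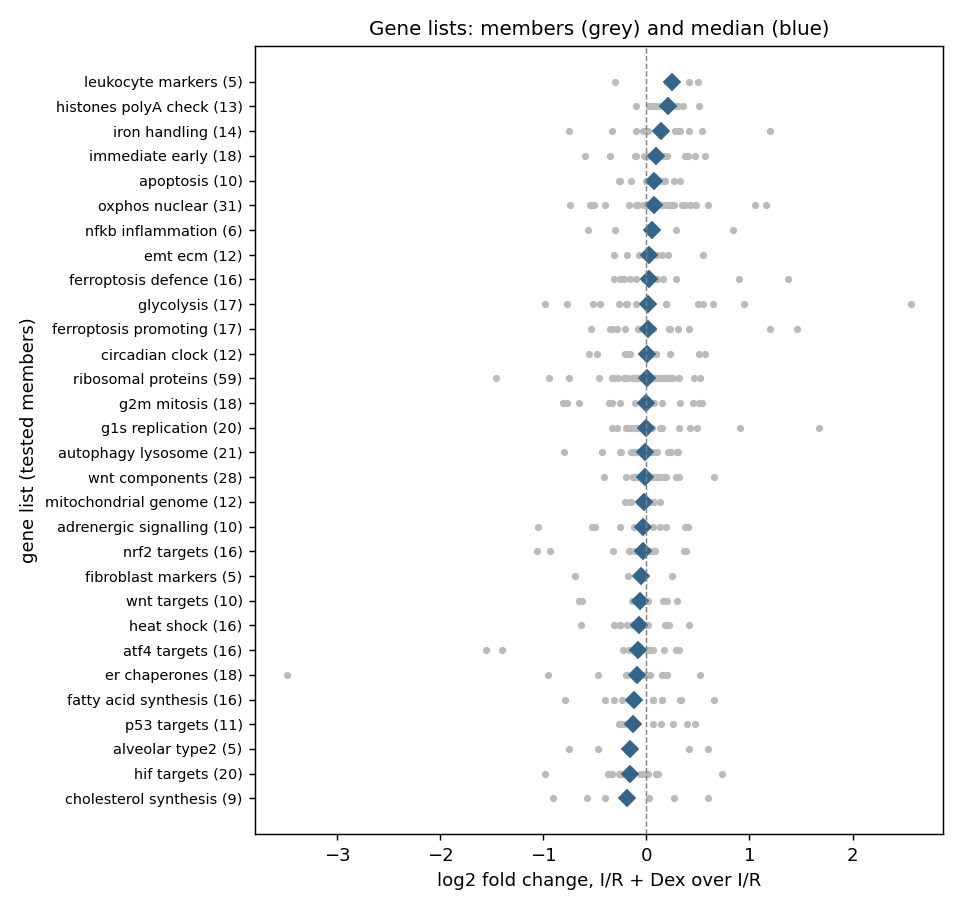
Log2 fold changes of I/R + Dex over I/R (horizontal axis) of the tested members (grey points) and their median (blue diamonds) for the 30 tested gene lists (vertical axis, number of tested members in brackets). Medians ran from -0.19 for cholesterol synthesis to 0.25 for leukocyte markers, and 0 lists passed the threshold in camera.

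At transcript level, edgeR called 0 of 9882 tested transcripts, with a smallest adjusted p = 0.0702 and 289 transcripts at an unadjusted p under 0.05, and DESeq2 called 73. Without a filter edgeR called 12. In data simulated at this depth with the trended dispersion, edgeR recovered 0% of 4-fold transcript changes, and DESeq2 recovered 1.52% of them and called 4 unchanged transcripts. These shares do not hold for transcripts with a smaller spread than the trend. Among the transcripts with the lowest p, those of Tax1bp1 and Creld1 came in pairs. For Tax1bp1, an autophagy receptor gene on chromosome 6, the coding transcript had 359, 404 and 432 counts in I/R and 16, 6 and 15 in I/R + Dex, while a transcript with a retained intron had 0 counts in I/R and 396, 325 and 371 in I/R + Dex, at least 135-fold higher against a floor of 3 counts per library. The gene total was 1195 and 1130 counts. For Creld1, the coding transcript had 84, 83 and 75 counts in I/R and 0 in I/R + Dex, and one with a retained intron 0 in I/R and 78, 53 and 77 in I/R + Dex, with gene totals of 252 and 242.

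Coding transcripts of Ilf2 and Ccnc were at least 131-fold and 33.5-fold lower in I/R + Dex. Gene totals were 1341 and 1143 counts for Ilf2 and 3904 and 3274 for Ccnc. A transcript of Ilf2 with a retained intron, chosen after its values were seen, went the other way. It had 0, 3 and 0 counts in I/R and 400, 173 and 386 in I/R + Dex. A coding transcript of the ribosomal protein gene Rpl24 had 742 ± 48.1 and 323 ± 33.5 CPM, with a gene log2 fold change of 0.04. One of Epn1 had 62.1 ± 6.54 and 175 ± 7.97 CPM, with gene totals of 846 and 1286 counts (log2 fold change 0.75, edgeR adjusted p = 1). A transcript of Son subject to nonsense-mediated decay was at least 52-fold higher in I/R + Dex, with gene totals of 7708 and 5932 counts. One of Gm21988 was at least 75.3-fold higher, and here the gene total moved as well, from 13 to 616 counts (log2 fold change 5.69 ± 0.61, SE, edgeR adjusted p = 0.0538). With 0610010K14Rik added, its 1 counted copy under the copy rule, the log2 fold change was 2.92 ± 0.23 (SE, edgeR adjusted p = 0.0254). In the reference annotation Gm21988 overlaps Rnasek on the same strand. Rnasek, chosen after its values were seen, had 257 to 261 counts in I/R and 25 to 77 in I/R + Dex (edgeR adjusted p = 0.287). Its totals were 777 counts in I/R and 137 in I/R + Dex, a fall near in size to the rise of Gm21988. Movement of reads between the overlapping genes was not tested and may account for the rise of Gm21988. Each of the 10 transcripts named by the rule had an edgeR adjusted p between 0.0702 and 0.118.

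The authors' deposited table lists 104 of 18021 transcripts as significant, 46 higher and 58 lower in I/R + Dex, which matches an adjusted p under 0.05 and an absolute log2 fold change of at least 1 for every transcript. In the authors' deposited table, 51 of the 104 had a mean FPKM of 0 in a group. They belong to 90 genes, of which 4 passed the gene-level test in edgeR and 62 had a gene total that differed by less than 1.5-fold. For the 53 with a mean above 0 in both groups, the median absolute log2 fold change was 3.74 in the authors' deposited table, and it was 0.18 for the totals of their 49 genes in edgeR. Pcbp2, an iron chaperone gene chosen after its values were seen, had a transcript with 0 counts in I/R and 504, 814 and 302 in I/R + Dex. Another had a log2 fold change of -2.79 in the authors' deposited table, while the gene had -0.03 in edgeR. Among the other list genes with a significant transcript, those of Shmt2 and Rpl3 had -1.99 and -1.88 there, and the genes -1.56 and -1.46 in edgeR. The genes Atp5c1, Rpl24 and Rps24 had 0.01, 0.04 and -0.32 in edgeR.

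In the authors' deposited enrichment tables, the GO term with the smallest adjusted p was nuclear part, with 54 of 103 items (adjusted p = 1.52e-05), against a background of 106170 items. Among the 18021 transcripts of the authors' deposited table, which could have been called, the annotation nucleus was found in 38.5% of the significant and 37.5% of the other transcripts (Fisher's exact test, two-sided p = 0.84). Only the terms given directly for a transcript were searched, without the terms below them, so this did not retest nuclear part. In the same exact test, nucleoplasm was found in 30.8% and 19.8% (p = 0.009, adjusted p = 0.027 over 3 terms), and ribosome terms in 6.73% and 4.38% (p = 0.226, adjusted p = 0.339). This test counts transcripts of a gene as independent, and the significant ones came from genes with more listed transcripts, a median of 3 against 2, and more counts, 1102.5 against 433. With each gene counted once, nucleoplasm was found in 35.6% of the 90 genes and in 25.3% on average of genes matched for the number of listed transcripts and the count (permutation test, two-sided p = 0.0374, adjusted p = 0.112 over 3 terms). These 3 terms were chosen after the deposited enrichment had been seen, and the test by gene after the test by transcript. Of 97 KEGG pathways in the authors' deposited table, 0 had an adjusted p under 0.05, the smallest being 0.429 for Ribosome. The table lists 1 of 47 items under Ferroptosis and 2 of 47 under Wnt signalling (adjusted p = 0.662 for both).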

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

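The alternatives that add copies or match list genes by symbol alone were chosen after the results had been seen. Against 5 genes in edgeR, DESeq2 called 17, limma voom 1, limma on log2(FPKM + 1) 8 and on log2(FPKM + 0.1) 3, and leaving out 1 library gave 0 to 4, with fewer samples in each fit. Adding near-identical copies gave 5 genes, 4 of them shared and Gm21988. The counts of Rnasek, which overlaps Gm21988, were not added to it. The looser copy rule, which was tried first, gave 0, with a smallest adjusted p of 0.0523 in edgeR. The replicate block gave 0. Deviations of libraries with the same number correlated at 0.02, -0.01 and -0.00415, so no pairing by number was seen. Such low correlations cannot exclude a shared culture or day. Other scalings and filters in edgeR and a minimum fold gave 5 to 7 genes that included the 5, and limma on log2(FPKM + 1) without a filter gave 6, 2 of them shared. For lists, fry with genes matched by symbol alone, tried first, called 1, the integrated stress response, lower in I/R + Dex (adjusted p = 0.0356, against 0.44 with synonyms), and all other settings called 0, the block included. For transcripts, no filter gave 12, DESeq2 73 and leaving out 1 library 0 to 3, with 3 without I/R replicate 3 and 1 without I/R + Dex replicate 1. The block gave 0.

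Of 90 values of the 5 genes called in edgeR, 41 stayed past the threshold and 49 did not, and all kept their direction. Of 18 settings each, both copy rules included, the call was lost in 8 for Ubald2, 11 for Mrps2, 9 for Rbm15b, 9 for Utp4 and 12 for Mboat7. Of 1163 values of the 65 other named genes, 1150 kept direction and side of the threshold. Rpl3 passed it without a filter (adjusted p = 0.0243 in edgeR) and in DESeq2 (0.00963), while adding its copies, with 65.1% of the counts, took its log2 fold change from -1.46 to -0.3153 (adjusted p = 0.999 in edgeR). Signs turned for genes that had not passed. Leaving out 1 library, log2 fold changes ran from -0.1098 to 0.0111 for Ctnnb1 (highest without I/R + Dex replicate 3), from -0.2817 to 0.0304 for Tcf7l2 (without I/R + Dex replicate 2, and 0.0199 without I/R replicate 1), from -0.0737 to 0.1051 for Slc7a11 (lowest without I/R + Dex replicate 3, and -0.0182 without I/R replicate 1) and from -0.2745 to 0.0886 for mt-Co2 (highest without I/R replicate 1). With copies added, Vkorc1l1 gave -0.0829 and Bcl2l2 -0.831, and under the looser rule these gave -0.086 and -0.8346 and Slc7a11 -0.0392. The cause of these changes was not tested.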

Other observations

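Tests on copies, on other splits, on transcripts and on other mouse cell types were chosen after the result was seen, while the bounds for abundant and non-coding genes were written before their levels were computed, though after epithelial genes had been seen at 0 counts. A first bound for the sum of Ubald2 and its copy, a log2 fold change of 1, would have been met with or without movement of reads, since the copy held most of the counts, and was replaced.

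Beyond the groups compared, the libraries held few counts for genes of epithelial identity. An exception was Tjp1, at 383 CPM. Genes of 3 lists written from general knowledge after epithelial genes had been seen included Actb, at 8656 CPM, Ddx5, at 8820, Eef1a1, at 6329, and Ywhaz, at 177, as slowly evolving. Those listed as faster evolving included Lgals1, at 2.32 CPM, and Cd63, at 5.76, but also Tmsb10, at 692, Lamp1, at 521, and Anxa2, at 319, and among non-coding RNAs Malat1 stood at 17.2 CPM. Gapdh itself had 7 to 322 counts, while its 120 counted copies together had 14280 to 18538 per library, 99% of the family. Tjp1, Gapdh and the genes given from these lists were chosen after their values were seen.

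The first pattern is the set of 5 genes past the threshold in edgeR. For Ubald2, reads that only moved from its copy Gm7367 would leave the sum at 0, while a copy held at its I/R level would give 0.67. The sum had a log2 fold change of 0.49 (95% interval 0.17 to 0.81, and 0.49 with 0.16 to 0.81 under the looser copy rule). By this bound the value goes against such movement as the whole rise. The evidence is weak, since the interval was not adjusted for the choice of Ubald2 by its rise in the same libraries. In edgeR the sum had an adjusted p of 0.999. Movement as a part stays open, as the copy's own log2 fold change was -0.32 ± 0.15 (SE). For the other 4 genes, annotated copies with a count numbered 0. Where a gene had a coding transcript, only its coding transcripts were searched. This argues against copies of the coding transcripts of Rbm15b and Mboat7. It cannot decide for Mrps2 and Utp4, since the counts of Mrps2 and most of those of Utp4 lay on other transcripts. Over all families the median within-group correlation of a gene and its copies was -0.134 (one-sided p = 0.0509 from 1000 shuffles) and -0.126 under the looser rule (p = 0.0649), which leaves a general exchange open. Some of these families joined different genes. The 10 splits of the 6 libraries cannot give a share under 0.05. Of these, 2 gave as many genes, with 5 for the real split and 5 for the highest other, and in DESeq2 5 gave as many, with 17 and 34. Genes at an unadjusted p under 0.05 in edgeR numbered 251 in the real split and 271 to 298 in the others. Correlations of log-CPM averaged 0.922 between groups, 0.924 within I/R and 0.919 within I/R + Dex. The libraries did not separate by group in these measures, and an effect of dexmedetomidine on these genes stays open.

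The second pattern is a set of 25 transcripts with at least 30 scaled counts in every library of a group and at most 3 in every library of the other, 11 in I/R and 14 in I/R + Dex. Reads assigned to one or another transcript of the same gene may account for many, since 22 of the 25 had a gene total that moved by less than 1.5-fold. A true change of splicing would give the same value and was not told apart from assignment for these 25. The other splits, which mix the groups, gave 10 to 25 such transcripts. Within I/R, a coding transcript of Gpx4 had 0, 634 and 0 counts and another 392, 0 and 438, chosen after their values were seen. A switch within I/R cannot come from dexmedetomidine. The 10 splits cannot give a share under 0.05. They gave 25 such transcripts for the real split and 25 for the highest other, with 2 splits at that number, 73 and 86 transcripts in DESeq2, with 4 splits as high, and 0 and 6 in edgeR, while lists gave 0 and 1, with 10 splits at least as high in both.

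The third pattern is the few counts for genes of epithelial identity. Reads of another mammal in place of mouse reads are a hypothesis for this, since 16 abundant genes with faster evolving sequence, listed from general knowledge, had a median of 15.1 CPM, under the bound of 50 CPM, against 1720 CPM for 16 slowly evolving ones, but 3 of the faster evolving genes were above 100 CPM and similarity between species was not measured. Of these 16 faster evolving genes, 4 also stood in a fixed list, and without them the median was 10.9 CPM. Non-coding RNAs, at 4.86 CPM, fell between the bounds of 2 and 20 CPM and left it open, and lists of mouse fibroblast, leukocyte, endothelial and alveolar type 1 genes had medians of at most 2.19 CPM, which decides nothing on those cells, since alveolar type II and epithelial junction genes had medians of 0.13 and 0 CPM. Which organism it could be was not tested, and a counting step that loses reads of some genes was not tested either.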
